A study of Drosophila melanogaster with 5 samples.

How the data were processed

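Hemocytes, the circulating blood cells of the fly Drosophila melanogaster, were profiled in larvae of the last stage before pupation on Affymetrix Drosophila gene expression arrays. There were 5 arrays, 1 for the control strain and 1 for each of 4 mutant stocks. The stocks were a loss-of-function line of split ends (spen), loss-of-function stocks of Enhancer of split (E(spl), stock 199) and Suppressor of Hairless (Su(H), stock 417), and a gain-of-function stock of the epidermal growth factor receptor (EGFR, stock 1564), each named as in the labels. Which alleles the E(spl), Su(H) and EGFR stocks carry, and whether their larvae were homozygous, could not be worked out. The design text set each mutant against the control. Per the labels' protocols, each array drew on blood cells of 200 to 300 larvae, which gave 1.0 to 1.3 µg of total RNA. The RNA went through an amplification kit (RiboAmp) before labelling, and 1 µg entered the labelling.

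The authors deposited 1 table of 18952 probe sets by 5 arrays, with values between 2.54 and 14.74 that fit a log2 scale, and they were used as log2 levels. The submitters' processing notes name RMA, a method that corrects background, quantile-normalises and summarises the probes of a set, and GCOS, the scanner software. Which role each played, with which version and settings, is not given in the sources used here. The table had no missing values. RMA would bring the arrays to a common distribution and so remove a shift of most genes in 1 direction. The deposited arrays did not share 1 distribution exactly, with lower quartiles of 3.55 (control) to 3.66 (spen) and medians of 4.46 to 4.54, so how far such a shift was removed is not known.

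Control probe sets of the manufacturer (183) were left out of all comparisons and used only for array quality, which left 18769 probe sets. Genes were named from the platform annotation. It gave 1 gene for 13647 probe sets, several genes for 402 and none for 4720, and no gene was named from a probe set with several or none. No symbol needed an update through its gene identifier in the Release 6 gene table, from which no coordinates were taken. The named probe sets covered 11982 genes, of which 1094 had several probe sets. Genes of the fixed lists without a symbol in this annotation are unnamed here. They include Su(H) itself, E(spl)m8-HLH, N and Dl.

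For each mutant, the difference of log2 levels (mutant minus control) was taken per probe set. A probe set was counted as higher or lower if the difference was at least 1 in size (2-fold) and its level on at least 1 of both arrays reached 4.50, the median of all levels. For gene lists, each gene took the mean of its probe sets. The median difference of a list was placed among 10000 random lists of the same size matched on mean level in 20 bins. A list was said to stand apart below the 2.5th or above the 97.5th percentile, which describes these arrays and is not a p-value. For lists of random genes, 1.55 of 31 lists per mutant would lie beyond these bounds, and 7 did in spen, 8 in E(spl), 7 in Su(H) and 10 in EGFR. Members of a fixed list may move together, some genes are in several lists, and all comparisons share 1 control array. The larger numbers are therefore not evidence beyond chance. There was 1 array per group, so there were no replicates, no test could be made, and no p-value, standard deviation between animals or false discovery rate is given. Words such as higher and lower describe these arrays only.

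Genes were named by a rule: the mutated gene, the 10 genes with the largest positive and the 10 with the largest negative difference in each comparison, up to 4 members of each list with the largest difference in size, and the 10 genes with the largest smallest difference shared across mutants. A gene was named by its probe set with the largest difference. Where the level on the dimmer array lay below the highest Bacillus control probe set of that array, the named difference was taken against that control and is a lower bound, written as at least. The order of genes, list medians and counts used the measured differences. The 31 lists, with 524 entries of which 387 were named on the array, were plasmatocyte, crystal cell, lamellocyte, lymph gland progenitor and niche, proliferation and replication, E(spl) complex, Notch pathway, EGFR pathway, antimicrobial peptides, Toll and Imd pathways, JAK/STAT and Turandot, JNK pathway and wound response, phagocytosis, extracellular matrix, coagulation and melanization, cytoskeleton and adhesion, ribosomal proteins, heat shock proteins, glycolysis, oxidative phosphorylation, ecdysone response, detoxification, fat body, muscle, salivary gland, gut, epidermis and cuticle, imaginal disc epithelium, nervous system, germ line and testis, and dosage compensation RNAs. Groups, comparisons, lists, thresholds and most alternative settings were fixed before the data were examined.

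Because the 4 comparisons shared 1 control array, overlaps were set beside 100 simulated draws of unchanged mutant arrays against that array, with noise taken from the spread between the mutant arrays at similar level. That spread holds real differences between mutants, so the simulation overstates noise. The overlap of independent lists was given as well. As a measure of probe set error, the spread of differences among probe sets of 1 gene was computed. It measures neither animals nor RNA preparations.

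The counting and list steps were tested on simulated data for all 18769 probe sets. For the spen comparison, 93.0% of probe sets altered by 1.5 log2 units and 97.0% of those altered by 3 were recovered, with 15 unaltered probe sets past the threshold. Recovery of probe sets altered by 1.5 was 92.0% for E(spl), 90.0% for Su(H) and 94.0% for EGFR. The simulated noise had an SD of 0.30 for spen and 0.32 for Su(H), set from the median deviation over all probe sets. Probe sets of 1 gene spread more, with a pooled SD of 0.52 in spen and 0.63 in Su(H). The simulated figures are therefore no error rate for these arrays. Alternatives were array-median subtraction, removal of a loess trend (span 0.4), renewed quantile scaling, no level filter, a filter on the mean level, a 3-fold threshold, counting genes, the highest probe set of a gene, list members above the filter only, and the mean of the other 3 mutants as reference. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.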

Results

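RNA levels in larval hemocytes were compared between a control strain and 4 mutant stocks, with 1 array each. Hemocytes of the last larval stage are mostly plasmatocytes, which engulf particles, with a minority of crystal cells, which carry prophenoloxidase for melanization, and rare lamellocytes, large flat cells that encapsulate foreign bodies. Array medians ran from 4.46 (E(spl)) to 4.54 (control). Signal was high for blood cell genes on the control array, with Hml, a hemocyte coagulation protein, at 13.93 and PPO1, a prophenoloxidase of crystal cells, at 14.26. Bacillus control probe sets, which give the background, had medians of 3.17 to 3.28 and reached at most 4.33 on the control array and 4.78 on the spen array.

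RNA quality differed between arrays. The 3' probe set exceeded the middle probe set, averaged over actin, eIF-4a and GAPDH, by 1.53 log2 units on the control array, 1.69 on spen, 1.84 on EGFR, 2.10 on E(spl) and 2.51 on Su(H). At GAPDH alone, E(spl) (2.22) was close to the control (2.20). The 3' to 5' difference did not follow this order. It was highest on Su(H) for all 3 genes (9.43, 8.50 and 6.37). E(spl) (8.69, 7.98 and 5.76) was close to or below the control (8.64, 8.31 and 5.79). The 5' probe sets of actin and eIF-4a stood at 4.63 to 5.85, near the highest Bacillus controls. Their 3' to 5' difference is therefore limited by background. Hybridisation spikes had a median difference from the control array of 0.40 on spen and −0.49 on EGFR, against 0.08 on E(spl) and 0.11 on Su(H).

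The mutated genes were read on every array as a check of the labels. spen, which encodes an RNA-binding nuclear protein, stood at 9.79 on the control array and at 4.90 on the spen array, 29.7-fold lower. It was at 10.35, 10.75 and 9.14 on the E(spl), Su(H) and EGFR arrays. A second spen probe set lay near background on all 5 arrays, with 2.98 on the control array, and carries no information. Egfr stood between 3.89 and 4.41 on all 5 arrays, below the level filter, so the EGFR label could not be checked from it. The E(spl) and Su(H) labels could not be checked either, because the probe sets of E(spl)m8-HLH and Su(H) are unnamed here. Of the other E(spl) complex genes, E(spl)mbeta-HLH and E(spl)m3-HLH are basic helix-loop-helix targets of Notch signalling. E(spl)mbeta-HLH was at 9.88 on the control array. It differed by −0.66 in spen, 0.36 in E(spl), 0.43 in Su(H) and 0.40 in EGFR. E(spl)m3-HLH differed by −1.08, 0.52, 1.67 and 2.03 in the same order.

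More probe sets were lower than higher than the control by at least 2-fold in every mutant. In spen, 307 were higher and 1364 lower of 10056 that passed the level filter. In E(spl), 691 were higher and 1427 lower of 10037. In Su(H), 757 were higher and 1396 lower of 10102. In EGFR, 486 were higher and 994 lower of 9932. The higher share of the differing probe sets was 18.4% in spen, where renewed quantile scaling gave 571 higher and 1130 lower (33.6%), and 32.6%, 35.2% and 32.8% in E(spl), Su(H) and EGFR. Against the mean of the other 3 mutants in place of the control, the higher share of passing probe sets exceeded the lower one in E(spl) (4.05% and 3.35%), Su(H) (4.71% and 2.04%) and EGFR (6.34% and 3.67%), and not in spen (6.45% and 8.68%). Against the spen array it did so in all 3 other stocks, with 10.17% and 7.47% in E(spl), 10.07% and 7.49% in Su(H), and 12.01% and 7.38% in EGFR, so the excess of lower probe sets in these 3 depended on the control array as reference. A probe set lower in every mutant cancels against a mutant reference, so this does not decide whether the control or the mutants differ. Differences of probe sets of 1 gene had a pooled SD of 0.52 in spen, 0.59 in E(spl), 0.63 in Su(H) and 0.55 in EGFR, so a 2-fold difference of a single probe set lay within 2 such SDs. In genes with several passing probe sets, 71.3% of those past 2-fold in spen had all others of the same sign. This share was 79.9% in E(spl), 78.8% in Su(H) and 72.2% in EGFR. Fewer had all others at least 0.5 log2 units off in that direction. That share was 36.2% in spen, 58.3% in E(spl), 54.8% in Su(H) and 39.1% in EGFR.

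**Figure D1:**
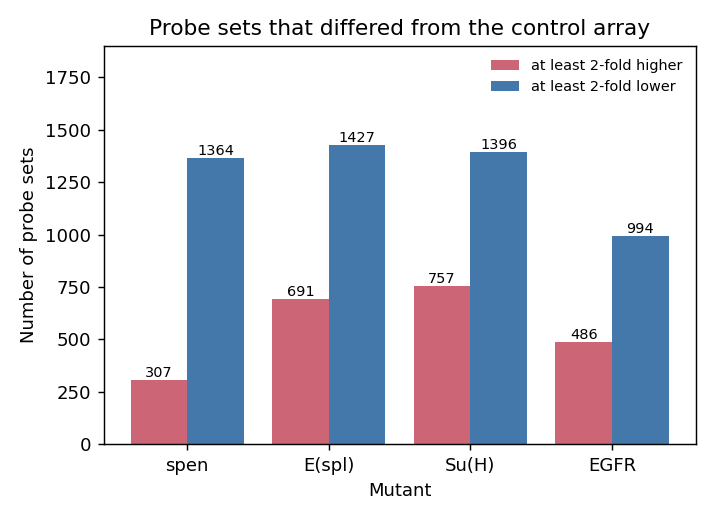
Bars give the number of probe sets (y axis) at least 2-fold higher (red) or lower (blue) than the control array for each mutant stock (x axis), 1 array per group. In all 4 stocks the lower bar is the taller, from 994 in EGFR to 1427 in E(spl).

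The comparison of spen with control asked what hemocytes of the spen loss-of-function line express. Salivary glue protein genes were among the highest: Sgs4 was 102-fold, Sgs7 33.8-fold, Sgs5 27.1-fold and Sgs3 17.8-fold higher in spen, and Eig71Ee, an ecdysone-induced gene, was 18.8-fold higher. Of the crystal cell markers, CG17109 was 45.7-fold lower, while CG7860 differed by 0.53. NimC4, a receptor for the uptake of dying cells, was 11.7-fold higher, and fng, a glycosyltransferase that modifies Notch, was higher by 3.34 on the log2 scale. Among the lowest genes beside spen itself were salt (at least 33.3-fold), CG10513 (at least 17.5-fold), CG11892 (at least 17.2-fold), Fst, a cold-induced gene (25.5-fold), AttD, an attacin (at least 14.2-fold), CG31272 and CG6733 (each at least 12.9-fold) and CG7768 (17.0-fold, its other probe set at −0.47). The highest genes also held CG15404 (at least 15.2-fold), obst-J, a chitin-binding protein gene (12.7-fold), CG31698 (at least 10.4-fold) and 1 of 2 Rnf11 probe sets (at least 12.8-fold), whose other probe set differed by −0.15.

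In spen, crystal cell genes had a median difference of −0.71 (0.04th percentile of matched random lists). Of the 8 above the level filter, 2 were lower by 2-fold and 6 differed by less; CG10469 differed by −1.45, peb, a zinc finger factor, by −0.81, PPO2 by −0.71 and PPO1 by −0.43. Cell cycle and replication genes had a median of −0.55 (0.01th percentile), with tum, a cytokinesis gene, at −2.49, CycB, a mitotic cyclin, at −1.61 and aurB at −1.45. Of these 17, 3 were lower by 2-fold and 14 differed by less. Plasmatocyte markers had a median of 0.10 and did not stand apart, and 12 of 13 differed by under 2-fold. The exception was NimC2, a receptor of the phagocytosis family, higher by 2.38. Lamellocyte markers had a median of 0.16 and did not stand apart, with 8 of 12 above the control. ItgaPS5, an integrin, was at −1.03 and shot, a cytoskeletal linker, at −1.41, while ItgaPS4 was at 0.80 and Drip at 0.45. All 8 salivary gland genes above the filter were higher by 2-fold, and the list median was 3.14 (100th percentile). Germ line and testis genes had a median of −2.01, with Mst84Da at −4.07 and ocn lower by at least 3.79. Also apart were fat body (−0.47, with 1 of 11 genes lower by 2-fold), coagulation and melanization (0.26, though 2 genes were higher and 4 lower by 2-fold; Lectin-galC1 lower by at least 2.30, Sp7 at 1.98) and epidermis and cuticle (0.30, with 4 of 11 genes above the filter).

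For E(spl) against control, the question was what differs in a stock labelled as loss of function for Enhancer of split, a target of Notch signalling. ninaD, a scavenger receptor for carotenoid uptake, stood at 12.06 in E(spl) and at 3.51, not above the Bacillus controls, in the control, and was at least 212-fold higher. Zip102B, a zinc transporter gene, was 64.7-fold higher, both Rnf11 probe sets were higher (by at least 4.88 and 4.56), and Scp2, a calcium-binding protein gene, was at least 35.4-fold higher. Lowest were CG30098 (85.9-fold), CAH7, a carbonic anhydrase gene (76.0-fold), santa-maria, a scavenger receptor gene of the carotenoid pathway (51.4-fold), and Fbp1, a storage protein receptor gene of the fat body (30.3-fold). Other high genes were PMCA, a calcium pump (at least 26.9-fold by 1 of 3 probe sets, the others at 1.02 and 1.08), Rbm13 (28.4-fold), Ret, a receptor tyrosine kinase (at least 22.4-fold), CG31248 (at least 15.8-fold), Ugt37A3 (at least 17.97-fold) and Ttc26 (at least 13.2-fold). Other low genes were Eig71Ea (at least 17.8-fold), CG33458 (30.9-fold), CG30428 (at least 17.2-fold), CG33181 (21.7-fold), Pgant8 (21.2-fold) and bib, a neurogenic gene (at least 17.8-fold).

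Cell cycle and replication genes were higher in E(spl), with a median of 1.15 (100th percentile); 11 of 17 were higher by 2-fold and 6 differed by less. CycB differed by 1.86, Orc1, an origin recognition gene, by 1.34 and Mcm5, a replicative helicase gene, by 1.33. Crystal cell markers had a median of 0.56 (99.9th percentile), with lz, the Runx factor of the crystal cell lineage, higher by at least 2.57, peb by 2.10 and CG7860 by 1.89; 4 of 10 were higher by 2-fold. Lamellocyte markers had a median of 0.91 (100th percentile), and 6 of 12 were higher by 2-fold, among them Drip, an aquaporin gene (2.64), ItgaPS5 (2.09) and atilla, a lamellocyte surface protein gene (1.98), while betaTub60D differed by −1.79; against the mean of the other 3 mutants the median was −0.028. Plasmatocyte markers had a median of 0.02, and NimC2 alone passed 2-fold, lower by at least 3.77. Muscle genes had a median of 1.06 (100th percentile), with Tm2 at 3.39, Mlc1 at 3.38 and up at 3.35. Salivary gland genes had a median of −0.98 and germ line and testis genes of −2.20, with betaTub85D at −3.44. Ecdysone response genes had a median of −0.30 (4 lower and 1 higher by 2-fold, MsrA at −2.75) and detoxification genes of 0.28 (2 higher and 1 lower by 2-fold, Cyp6w1 at 3.37). These differences stood beside a 3' to middle difference 0.57 log2 units above that of the control array. The 3' to 5' difference showed no such excess. With 5' probe sets of actin and eIF-4a near background, it does not argue against one.

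Su(H) against control addressed a stock labelled as loss of function for the transcription factor that acts downstream of Notch. Of the lamellocyte genes, only atilla was among the 10 highest (16.9-fold), while ItgaPS4, an integrin gene, was higher by 3.62 and CG15347 by 3.28. Jon99Fi, a digestive protease gene, was 87.5-fold higher, both Rnf11 probe sets were higher (by at least 7.29 and 6.42), and Zip102B was 42.9-fold higher. santa-maria was 43.0-fold, Eig71Ea at least 18.5-fold and CAH7 40.4-fold lower. The other highest genes were CG4607 (29.7-fold), Tdc1, a tyrosine decarboxylase gene (28.8-fold), CG3397 (23.4-fold), CG14610 (22.5-fold), CG17633 (17.2-fold) and CG7497 (16.3-fold). The other lowest were AttD (at least 20.3-fold), CG30098 (22.5-fold), Fbp1 (20.7-fold), CG17919 (19.7-fold), CG43446 (16.5-fold), CG4477 (at least 12.96-fold) and 1 of 2 probe sets of Bmcp, a mitochondrial carrier gene (at least 28.5-fold), whose other probe set differed by 0.00.

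In Su(H), lamellocyte markers had a median of 1.37 (100th percentile), with 6 of 12 higher by 2-fold and none lower by 2-fold. Cell cycle and replication genes had a median of 1.04 (100th percentile), with 9 of 17 higher by 2-fold, Orc1 at 2.02 and CycB at 1.77. Crystal cell markers had a median of 0.51 (99.9th percentile); CG7860 differed by 2.0, peb by 1.94 and lz by at least 1.39, and the 7 others by under 2-fold. Plasmatocyte markers had a median of −0.10, with NimC2 at −2.03. Muscle genes had a median of 1.57 (100th percentile) and 10 of 13 above the filter were higher by 2-fold, with Tm2 at 3.81, Mlc1 at 3.60 and up at 3.44. Gut genes had a median of 0.56 (100th percentile), 5 higher and 2 lower by 2-fold, with Jon66Ci at 2.53 and Jon99Ci at 2.11 beside Jon99Fi, while thetaTry differed by −1.78. Glycolysis genes had a median of 0.58 (99.9th percentile), with Hex-A at 1.29 and 9 of 10 genes under 2-fold. Germ line and testis genes had a median of −1.38, with ocn at −3.24 and Mst84Da at −3.02. The Su(H) array had the largest 3' excess of the 5, at 0.98 log2 units above the control.

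EGFR against control addressed the effect of receptor gain of function. lz was at least 8.57-fold higher in this stock, Rnf11 was higher by at least 7.76 and 7.28 at its probe sets, and Zip102B was 33.4-fold higher. CAH7 was 114-fold, CG30098 46.8-fold and santa-maria 37.8-fold lower. lectin-24A, a lectin gene, was at least 6.89-fold higher, MtnB, a metallothionein gene, 10.4-fold, stj, a calcium channel subunit gene, 10.1-fold, and Ilp7, an insulin-like peptide gene, at least 4.88-fold. CG14610 (12.2-fold), CG11893 (at least 5.60-fold) and 1 of 3 PMCA probe sets (at least 19.2-fold, the others between −0.50 and 0.50) completed the highest. Eig71Ea (at least 16.9-fold), CG17919 (38-fold), CG6293 (36.6-fold), CG13795 (32.7-fold), CG31272 (at least 16.8-fold), CG10513 (at least 22.8-fold) and NT5E-2, a nucleotidase gene (at least 25.1-fold), completed the lowest.

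Cell cycle and replication genes had a median of 1.19 in EGFR (100th percentile), with all 17 above the control and 11 by 2-fold; Orc1 differed by 2.32 and Mcm3 by 1.85. Lamellocyte markers had a median of 0.82 (100th percentile), with ItgaPS5 at 2.61, Drip at 2.33 and atilla at 2.32, and 5 of 12 higher by 2-fold. Crystal cell markers had a median of 0.33 (percentile 98.2), with CG7860 at 2.04, peb at 1.84 and CG17109 at −1.05. Plasmatocyte markers had a median of 0.16, with NimC2 at −2.70. Fat body genes had a median of −0.55 (0.17th percentile), 5 lower and 3 higher by 2-fold, with Fbp1 at −3.52, Fbp2 at −2.80, apolpp, a lipid carrier gene, at −2.72 and FASN1, a fatty acid synthase gene, at 1.25. Also apart were muscle (0.42, with 2 of 11 genes above the filter higher by 2-fold), E(spl) complex (0.37, with 4 of 10 genes above the filter and 1 past 2-fold), detoxification (0.29, against a mean of −0.22, with 2 genes higher and 2 lower by 2-fold), extracellular matrix (0.26, all 13 genes above the filter under 2-fold), germ line and testis (−0.48) and the 2 measured genes of the dosage list (1.00). The 2 genes of the dosage list were Sxl and msl-2, since roX1 and roX2 are unnamed here. Of the 3 Sxl probe sets, 1 differed by 1.55 in EGFR and the others by 0.13 and 0.36. No change of dosage compensation is read from this list. Against the mean of the other 3 mutants the muscle median was −0.45 and the germ line and testis median 1.26. The EGFR pathway list itself, with 16 genes, had a median of 0.07 and did not stand apart.

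**Figure D2:**
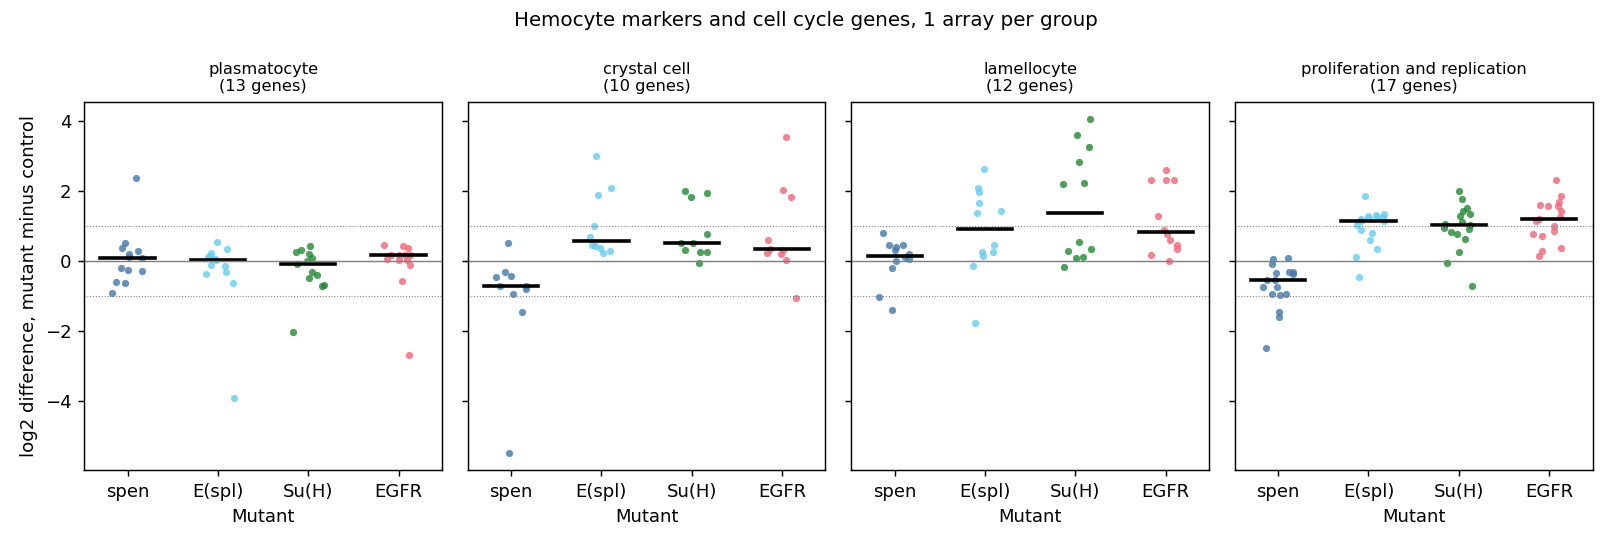
Each point is 1 gene, with its log2 difference from the control array on the y axis and the mutant stock on the x axis, 1 array per group; bars are list medians and dotted lines mark 2-fold. Cell cycle genes lie mostly above 0 in E(spl), Su(H) and EGFR (medians 1.15, 1.04 and 1.19) and mostly below 0 in spen (−0.55).

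Against the spen array in place of the control, 5 lists lay beyond the bounds for standing apart in each of the 3 other stocks. Crystal cell, cell cycle and lamellocyte genes were higher than in spen, and salivary gland and ecdysone response genes were lower. Lamellocyte medians were 0.67 in E(spl), 1.47 in Su(H) and 0.62 in EGFR, salivary gland medians −5.73, −3.77 and −3.27, and ecdysone response medians −0.37, −0.22 and −0.24. All 10 crystal cell markers lay above their spen value in each of the 3 other stocks, with medians of 1.42 in E(spl), 1.46 in Su(H) and 1.33 in EGFR. Of the 17 cell cycle genes, 16 lay above spen in all 3 stocks. All of these differences subtract the single spen array, so agreement across the 3 stocks is not independent. For crystal cell and cell cycle genes they also follow from the opposite signs against the control. fng and NimC2 were higher in spen and lower in the other 3, with fng at −1.65, −1.56 and −1.96 in E(spl), Su(H) and EGFR. CAH7 and santa-maria, far below the control in those 3 stocks, were higher in spen by 1.00 and 1.49. Between mutants, E(spl) and Su(H) were the closest pair, with 664 probe sets that differed by 2-fold, against 1721 for E(spl) and spen, 1728 for Su(H) and spen, 1928 for EGFR and spen, 1280 for EGFR and E(spl), and 1133 for EGFR and Su(H). The E(spl) and Su(H) arrays also had the largest 3' to middle differences (2.10 and 2.51) and the highest muscle medians against the control (1.06 and 1.57). Their closeness was not separated from shared RNA quality or tissue content.

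In all 4 mutants, 563 probe sets were lower than the control by 2-fold and 15 were higher. Simulated unchanged arrays against the same control gave 207 (171 to 235) and 156 (113 to 194), and independent lists would share 3.0 and 0.05. The observed 15 lay below every simulated draw. The simulated counts, here and below, are therefore no yardstick for an excess. The 3 Notch-related stocks, spen, E(spl) and Su(H), shared 930 lower (simulated 248) and 29 higher probe sets (simulated 188). E(spl), Su(H) and EGFR shared 691 lower (simulated 248) and 205 higher ones (simulated 189). Another 39 were higher in those 3 and lower in spen, and 27 were the reverse, against simulated 0.78 and 0.94. Each fold given next for a shared gene is the smallest over the stocks named. There, at least marks this smallest fold and need not reflect background. Beside Rnf11, genes higher in all 4 were led by Sxl, the sex-determination gene (at least 2.82-fold at 1 probe set). Next came CG9171 (at least 2.47-fold), Traf-like (at least 2.39-fold) and Slik, a kinase gene (at least 2.28-fold). Those lower in all 4 were led in measured difference by Eig71Ea (at least 13.00-fold), CG42717 (at least 3.61-fold), CG31272 (at least 8.14-fold) and CG4477 (at least 8.08-fold). In the Notch-related stocks, Pde11, a phosphodiesterase gene, was higher by at least 3.33-fold and TrxT, a thioredoxin gene of the testis, lower by at least 11.8-fold. Both passed 2-fold in the same direction in EGFR too, with log2 differences of 1.08 and −1.18.

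Differences of E(spl) and Su(H) from the control correlated across probe sets at r = 0.82, with a covariance of 0.46 against 0.19 simulated. This pair also had the largest 3' to middle differences and the highest muscle medians, which were not separated from it. E(spl) and EGFR gave r = 0.68 (covariance 0.31) and Su(H) and EGFR r = 0.70 (0.31). spen gave r = 0.51 with E(spl) (0.27), 0.51 with Su(H) (0.26) and 0.40 with EGFR (0.16), where simulated arrays gave r of 0.50 and a covariance of 0.19. The covariance of spen and EGFR lay below the simulated one, so no excess over the simulation is read from these values. Probe sets are not independent replicates, and part of each overlap may come from the single control array, which could not be split.

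**Figure D3:**
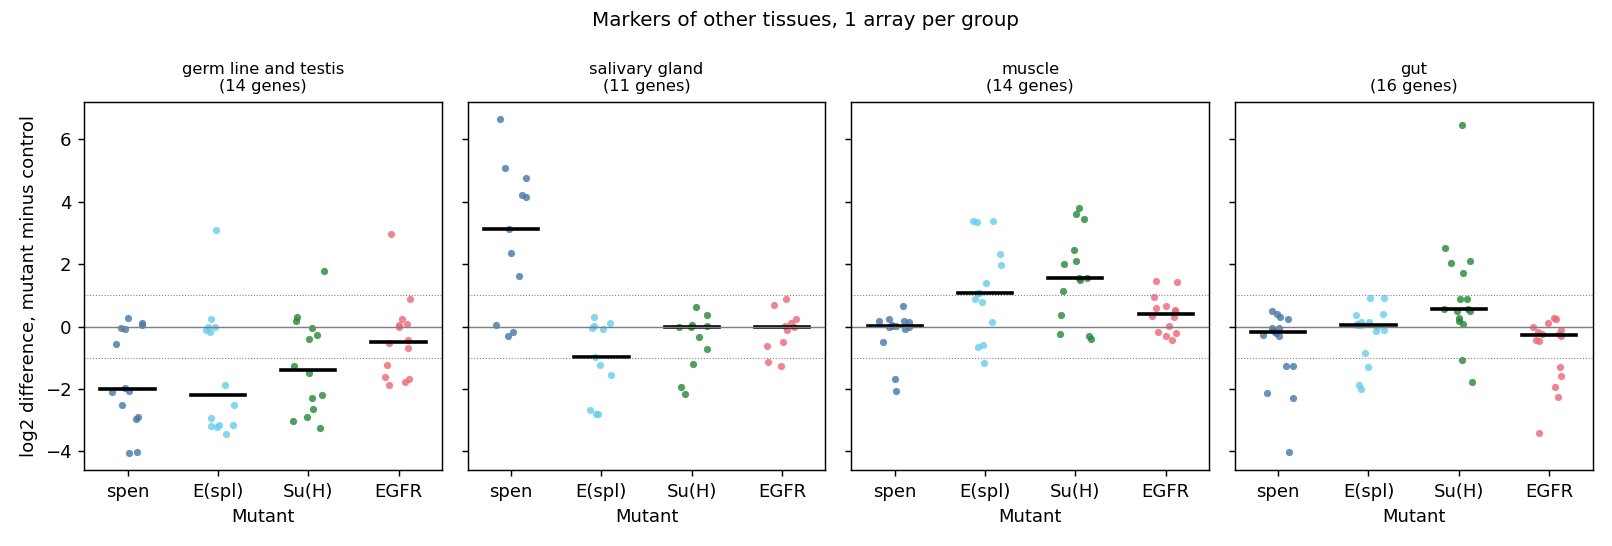
Each point is 1 gene of a list of another tissue, with its log2 difference from the control array on the y axis and the mutant stock on the x axis, 1 array per group; bars are list medians and dotted lines mark 2-fold. Germ line and testis medians lie below 0 in all 4 stocks (−2.01, −2.20, −1.38 and −0.48), and the salivary gland median reaches 3.14 in spen.

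Markers of other tissues moved with these comparisons. The 8 testis genes betaTub85D, Mst87F, Mst84Da, Mst98Ca, Mst98Cb, dj, ProtA and ocn were highest on the control array, where betaTub85D stood at 11.48, and differed least in EGFR, with betaTub85D at −1.22 there. bam, a germ line differentiation gene, was the only list member higher by 2-fold, at 3.11 in E(spl), 1.77 in Su(H) and 2.97 in EGFR. Antimicrobial peptide genes above the filter were lower in all 4 stocks at AttD, Drs and Mtk; Drs differed by −2.13 in spen, −1.08 in E(spl), −2.12 in Su(H) and −1.18 in EGFR, while CecB was at 2.18 in E(spl). The medians of the antimicrobial list were −0.31, −0.29, −0.12 and −0.30, and it did not stand apart. Over its members above the level filter alone, the medians were −1.91, −1.08, −2.12 and −1.62.

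The remaining lists did not stand apart in any mutant, and their medians in spen, E(spl), Su(H) and EGFR follow in that order. Signalling lists gave 0.12, 0.14, 0.18 and 0.05 for the Notch pathway, 0.00, 0.10, −0.12 and −0.03 for Toll and Imd, 0.23, 0.09, 0.13 and 0.12 for JAK/STAT and Turandot, and 0.14, 0.10, −0.01 and 0.14 for JNK and wound response. Blood cell lists gave 0.07, −0.01, −0.03 and 0.02 for phagocytosis and 0.05, −0.26, −0.11 and −0.05 for cytoskeleton and adhesion. Lymph gland genes gave 0.20, −0.06, 0.12 and 0.08, with only 3 of 8 genes above the filter. Ribosomal proteins gave 0.25, −0.02, −0.01 and 0.03, oxidative phosphorylation 0.03, −0.06, −0.07 and 0.19, and heat shock proteins 0.20, 0.22, 0.27 and 0.28. Imaginal disc genes gave 0.08, 0.08, 0.13 and 0.02 and nervous system genes 0.15, 0.06, 0.06 and 0.14. No direction is read from these medians, since the sign of 32 of 124 list medians turned under some scaling, none of them of a list that stood apart.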

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

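The alternatives with the spen array as reference, and without the probe sets lower in all 4 mutants, were chosen after seeing the data; the others were planned. Giving counts under another reference as shares of passing probe sets was also chosen after seeing the data. Each group had 1 array, so leaving out a replicate was not possible. No paired analysis was possible because each group had 1 array. The pseudocount was not varied because the values are log2. Subtracting array medians, dropping the level filter, filtering on the mean level and counting genes moved no count by over 1.5 times. The median difference over all probe sets in spen was 0.09 as deposited, 0.16 after array-median subtraction, 0.05 after quantile scaling and −0.02 after loess. Among lists that stood apart, no median turned sign under a scaling. Low signal limits the genes near background, with Bacillus controls at up to 4.78. The cause was not tested for any of the values below, except where the alternative itself uses a stricter threshold or leaves probe sets out.

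At a 3-fold threshold, higher and lower counts were 91 and 830 in spen, 263 and 889 in E(spl), 327 and 801 in Su(H), and 165 and 370 in EGFR. Shared counts at 3-fold were 1 higher and 167 lower in all 4, 3 higher and 590 lower in spen, E(spl) and Su(H), and 53 higher and 221 lower in E(spl), Su(H) and EGFR. Renewed quantile scaling gave 571 higher probe sets in spen and medians of 1.40 for cell cycle genes in EGFR and 0.29 for the Notch pathway in spen. Without the probe sets lower in all 4 mutants, the lower counts were 801, 864, 833 and 431 in spen, E(spl), Su(H) and EGFR. With the spen array as reference, the excess of lower probe sets turned round: the higher and lower shares of passing probe sets were 10.17% and 7.47% in E(spl), 10.07% and 7.49% in Su(H), and 12.01% and 7.38% in EGFR (4.89% and 10.01% with the control).

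With the mean of the other 3 mutants as reference, the higher and lower shares of passing probe sets were 6.45% and 8.68% in spen (3.05% and 13.6% with the control), 4.05% and 3.35% in E(spl) (6.88% and 14.2%), and 4.71% and 2.04% in Su(H) (7.49% and 13.8%), and 6.34% and 3.67% in EGFR (4.89% and 10.01%), so it turned round in all but spen. List medians under that reference were, in spen, 0.22 for plasmatocyte, −1.39 for crystal cell, −0.91 for lamellocyte, −1.82 for cell cycle and −0.13 for Notch pathway genes. In E(spl) they were 0.55 for cell cycle, 0.069 for E(spl) complex, 0.041 for EGFR pathway and 0.39 for antimicrobial genes, and the lamellocyte median was reversed, to −0.028. In Su(H) they were 0.83 for lamellocyte, 0.55 for cell cycle, −0.0082 for E(spl) complex and −0.031 for Notch pathway genes. In EGFR they were 0.43 for lamellocyte, 0.90 for cell cycle, −0.11 for Notch pathway and −0.035 for antimicrobial genes, and reversed to −0.45 for muscle and 1.26 for germ line and testis. Rnf11 was reversed in spen (−2.68) and in E(spl) (−1.08). Among the other lists and named genes, 115 values moved, 4 were reversed and 53 stayed, and only the reversed ones are given. Against the spen array, germ line and testis medians were −0.05 in E(spl), 0.14 in Su(H) and 1.44 in EGFR. With the control they were −2.20, −1.38 and −0.48.

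With only members above the level filter, antimicrobial medians were −1.91, −1.08, −2.12 and −1.62 in spen, E(spl), Su(H) and EGFR, and E(spl) complex medians were −0.87, 0.36 and 0.54 in spen, E(spl) and Su(H). With the highest probe set of each gene, medians were −0.73 for cell cycle and −0.11 for Notch pathway genes in spen and −0.071 for Notch pathway genes in Su(H). Loess gave −0.084 for the E(spl) complex and −0.0031 for the EGFR pathway in spen.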

Other observations

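All tests of explanations given here were chosen after the results they bear on had been seen. Some genes stood near background on some arrays and high on others. ninaD stood at 12.06 in E(spl) and between 3.51 and 5.54 on the other arrays. Zip102B stood at 11.37, 10.77 and 10.41 in E(spl), Su(H) and EGFR, and at 5.35 and 5.15 in the control and spen. CAH7, at 11.31 in the control and 12.31 in spen, stood at 5.07, 5.98 and 4.48 in E(spl), Su(H) and EGFR. At PMCA, 1 probe set was higher by at least 4.75, 3.19 and 4.26 in those 3 stocks while the other probe sets of the gene differed by at most 1.08. At Bmcp, 1 probe set was lower by at least 4.83 in Su(H) and the other by 0.00. These genes were picked from the named genes after their values were seen. Whether their differences came from the mutations or from other differences between the stocks was not tested.

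The genes that follow were also picked after their values were seen, and stand for no group. Idgf3 differed by −1.08 in spen and by 2.34, 1.94 and 1.57 in E(spl), Su(H) and EGFR. lectin-24A was not above the Bacillus controls in the control (3.78) and spen (4.44), and was higher than the control by at least 2.53, 2.60 and 2.785 in E(spl), Su(H) and EGFR. fon, a clotting protein gene, differed by −1.13, −1.83, −0.54 and −3.20. Sr-CIII, a scavenger receptor gene, differed by 3.53 in E(spl) and by −0.95 in spen. Cyp6g1 differed by −3.25, −0.80, −3.37 and −3.62. Cyp12a4 was lower by at least 2.71 in spen and differed by 0.68, 2.36 and −2.32 in the others. Cat, the catalase gene, differed by 0.72, −2.15, −2.04 and −0.76.

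In all 4 mutants more probe sets were lower than higher. Against the spen array, more probe sets were higher than lower in E(spl) (10.17% and 7.47%), Su(H) (10.07% and 7.49%) and EGFR (12.01% and 7.38%), so the excess there depended on the control as reference, and error of the control array stayed open. A reduction common to all mutants would cancel against spen too, so the turn-round does not decide between them. Testis RNA in the control preparation is a candidate explanation: testis genes were highest on the control array and differed least in EGFR, and among probe sets lower in the other 3 mutants EGFR had the smallest reduction in 89.4%, against 24% for spen, 8.43% for E(spl) and 7.63% for Su(H) in their own such sets. Any other source with the same order across arrays would give that result, and EGFR was also the mutant nearest to the control by count. A difference in the sex ratio of the larvae, on which the 3 Sxl probe sets bear unequally (1.49 to 1.77 at 1 probe set, at most 0.75 at the others), and an effect of the mutations stayed open and were not tested.

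Glue genes were higher in spen than in any other array, and salivary gland tissue in the spen preparation may explain them, but only sage, of the salivary gland genes other than the glue genes and Eig71Ee, was above the level filter, at a difference of 1.62, and fkh, ng1 and ng3 lay near background, so it cannot be told apart from expression of glue genes in other cells. A later stage of the spen larvae was tested by the ecdysone response list, whose median against the control was 0.050 with members on both sides. The same list was lower than in spen in the other 3 stocks, with medians of −0.37, −0.22 and −0.24 (13, 13 and 10 of 16 members lower), which goes with a later stage of spen than of those stocks, but against the control the list decides nothing, so a later stage cannot be told apart from the other explanations. An effect of spen loss stayed open as untested.

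Cell cycle genes had medians of 1.15 in E(spl), 1.04 in Su(H) and 1.19 in EGFR, with 11, 9 and 11 of 17 higher by 2-fold, and of −0.55 in spen, with 3 of 17 lower by 2-fold and 14 under 2-fold. Error of the control array alone is argued against by the differences from the spen array, which leave the control out. Their smallest median over the 3 stocks was 1.65, and 16 of 17 genes lay above spen in all 3. This follows from the opposite signs against 1 shared control and is no independent test. It leaves open how much the control array added to each median. All 3 differences share the single spen array, whose own error would give such differences too and was not tested. Stronger 3' bias as the only source is argued against in EGFR. In proportion to Su(H) it would give EGFR a median of 0.33, and the observed 1.19 exceeded that by 0.86. The SD of random medians was 0.15, but it does not measure the error of that proportion, which rests on 3 genes. A part of the rise from 3' bias stayed open in all 3 stocks. Lymph gland cells in the preparations cannot be told apart from this, because only 3 lymph gland markers were above the level filter, though none was higher by 2-fold: in E(spl), Su(H) and EGFR, Ance differed by −1.82, −0.65 and −0.81, Tep4 by −0.33, 0.40 and 0.46, and dome by 0.18, 0.26 and 0.11, with control levels of 12.17 at Ance and 13.18 at Tep4 that would hide a small share of such cells. An effect of the mutations and a difference in larval stage stayed open for these genes and were not tested. E(spl), Su(H) and EGFR carry stock numbers in the labels, and spen and the control do not. Each mutation came with 1 stock, so its effect cannot be told apart from other differences between the stocks.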
